A study of Danio rerio with 2 samples.

How the data were processed

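Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts accessible DNA and adds sequencing adapters to the cut ends. The samples were wild-type zebrafish (Danio rerio, strain AB/PS) at 2.5 hours post fertilization, the 256-cell stage. Per the labels' protocols, chorions were taken off with pronase, yolk was removed, 75000 cells went into each library, and an Illumina HiSeq was used for sequencing. The labels give 1 group with 2 biological replicates, so replicate against replicate is the only comparison between samples, and no condition can be contrasted with another.

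Each deposited file is a table of peaks from MACS 2.1.1.20160309, called on 1 sample at a time and not on pooled reads, per the file headers. Alignment with Bowtie2 2.2.1 and the Zv9 build are named in the submitters' processing notes. Per the file headers, tags were read in single-end mode, extended by 147 bp without a shift or a fragment model, at most 1 tag per position was kept, no control sample was used, the genome size was set to 1370000000 bp and the q cut-off was 0.01. The alignment names in the headers contain the word paired, although paired-end mode was off, and they carry different day tags for the replicates, whose meaning is not given in the sources used here. Extension without a shift places the summit downstream of the transposase cut rather than over it, which limits the precision of summit positions and can move peak ends. Keeping 1 tag per position lowers the tag number most where coverage is highest.

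The deposited pileup is a coverage signal, the number of extended tags over the summit, and it is not scaled to depth. Deposited fold enrichment is the ratio of that pileup to the local tag density of the same sample. The deposited scores are −log10 of a Poisson p-value and −log10 of its q-value at the summit, both from MACS. Peak length in bp is the last deposited measure used. All of these are the authors' values for single peaks and served here mainly to describe and rank peaks inside their own list. Between the lists, pileup and fold enrichment gave the tag densities compared below. Pileup and −log10 p also entered the cut-off and depth tests of the closing section. Per the file headers, replicate 1 had 15112091 tags, of which 5123112 (33.9%) remained after duplicates were removed, and replicate 2 had 16258120 tags, of which 5586367 (34.4%) remained. A redundant rate of 0.66 is given for both.

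Overlaps were counted with bedtools 2.31.1, and all other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Peaks were called shared when they overlapped by at least 1 bp. Sharing and clustering (a neighbour in the same list starting within 10 kb) were compared with 10000 random placements of the peaks inside their own chromosomes, one-sided, so 0.0001 is the smallest p these tests can give. Differences of medians between shared and unshared peaks had a two-sided permutation test with 100000 resamples, whose smallest p is 1e-05, adjusted by Benjamini-Hochberg over both lists. Peaks per chromosome were compared between replicates with Fisher's exact test, and with chromosome length by an exact binomial test, each adjusted over 25 chromosomes. Chromosome length was taken as the furthest peak end of either list, because no Zv9 genome was used here. Intervals for shares are Wilson intervals at 95% unless called exact, and they treat peaks as independent, although neighbouring peaks are not. The permutation tests of medians treat peaks in the same way.

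The number of deduplicated tags in the 10 kb around each summit was recovered from pileup and fold enrichment, since MACS divides by the local density. It came out whole within 0.01, or at the genome-wide mean that MACS uses as its floor, for 379 of 380 and 1095 of 1096 peaks. The genome-wide mean was 37.4 tags per 10 kb in replicate 1 and 40.8 in replicate 2. Poisson values recomputed from these numbers differed from the deposited −log10 p by at most 0.00023 and 4.9e-05. Tag density is given below as a multiple of the sample's own mean, which takes out depth. Intervals of density ratios are exact binomial intervals and cover counting error only.

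The regions named in the text follow a rule set before the data were examined. It takes the 20 shared peaks with the best rank by −log10 q in the list where they rank worse, the 5 best ranked unshared peaks of each list, and at most 10 windows of 100 kb with 5 or more peaks in either list. Regions named for their tag density were chosen after their values were seen. The tests of sharing, clustering and chromosomes were also run on simulated lists with the lengths of the real ones, and those of medians, chi-square and intraclass correlation on simulated values, but the tests of cut-off, depth scaling, nearness of replicate 2 peaks to replicate 1 peaks and dense windows of the closing section were not simulated. All 200 planted shared peaks were found, 1 of 100 unrelated list pairs had a sharing p under 0.05, and the chromosome with a planted excess was called, while 3 of 100 lists without any excess called a chromosome. The planted shared peaks were copies that still overlapped their originals, so finding them was fixed in advance. The planted chromosome excess was made by copying the peaks of a chromosome, and it was larger than the excesses reported below. Its call therefore does not show that excesses of the size reported below would be found. Lists without planted peaks were placed at random and unclustered. Their rates of false calls need not hold for clustered peaks like those of the real lists.

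Alternatives covered the overlap rule, stricter and equally long lists, merged peaks, other placements, other scores and each list on its own. Tests at transcription start sites, of 11 gene lists and of base composition had been planned, but they need an annotation or sequence of the files' build. They were not run, no gene is named, and peak positions are given on Zv9 as in the files.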

Results

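Accessible chromatin was mapped in whole wild-type zebrafish embryos at 2.5 hours post fertilization, when the embryo has 256 cells and the zygotic genome is not yet broadly transcribed. The series set out to describe accessibility across the genome before zygotic activation, with 2 biological replicates. Replicate 1 gave 380 peaks covering 97240 bp and replicate 2 gave 1096 peaks covering 240234 bp, a ratio of list lengths of 2.88 at a depth ratio of 1.09. Peaks lay on all 25 chromosomes in both lists. Median peak length was 188 bp in replicate 1 and 174 bp in replicate 2, median pileup at the summit was 30 and 18 tags, and median fold enrichment was 6.46 and 6.33.

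The first comparison asks which accessible sites were found in both replicates. The best ranked shared site was on chromosome 22 at 28947397 to 28947654, with a fold enrichment of 32.0 in replicate 1 and 29.6 in replicate 2, pileups of 93 and 92 tags and summits at the same base. A site on chromosome 11 at 35982474 to 35983108 followed, with fold enrichments of 23.4 and 22.3 and again no distance between the summits. On chromosome 17 at 53841343 to 53841644, the best ranked site of replicate 2 (rank 3 in replicate 1) had pileups of 83 and 110 tags and fold enrichments of 26.0 and 24.9. Further sites near the top of both lists were on chromosome 7 at 73909789 to 73910110 (18.0 and 18.3), chromosome 2 at 56692506 to 56692726 (24.7 and 24.3), chromosome 4 at 2134976 to 2135240 (23.8 and 21.5) and chromosome 21 at 41207700 to 41208162 (16.4 and 16.5). The 20 named shared sites lay on 13 chromosomes, none ranked worse than 23 in either list, and their summits were a median of 5.5 bp apart (range 0 to 216 bp). Their fold enrichments went down to 7.52 in replicate 1 and 7.03 in replicate 2. In each replicate, 14 of the 20 had at least 4 times the genome mean of tags in the surrounding 10 kb, the peak's own tags included. Among all peaks, 244 of 380 (64.2%) in replicate 1 and 421 of 1096 (38.4%) in replicate 2 reached this limit.

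Of the 380 replicate 1 peaks, 330 (86.8%, interval 83.1 to 89.9) met a replicate 2 peak, against a median of 0 and a maximum of 3 in random placements (permutation p = 0.0001, the smallest possible). Counted from replicate 2, 322 of 1096 peaks (29.4%, interval 26.8 to 32.1) met a replicate 1 peak, against at most 4 by chance. Over the 330 pairs the summits were a median of 17 bp apart (quartiles 6 and 51), and the median reciprocal overlap was 81.2%. The best unshared peaks of replicate 1 had a replicate 2 peak close by. Those on chromosome 20 at 24307479, chromosome 17 at 46622088, chromosome 14 at 17187692 and chromosome 22 at 42168860 missed it by 90, 94, 30 and 96 bp, and the one on chromosome 11 at 15193256 by 544 bp. In replicate 2, the best unshared peak was on chromosome 17 at 16714016 to 16714210 (rank 44, fold enrichment 15.4, pileup 32), with the nearest replicate 1 peak 19849345 bp away. Unshared replicate 2 peaks on chromosome 13 at 27386190 and chromosome 4 at 6590783 had fold enrichments of 12.8 and 11.4 and lay 688870 and 5767 bp from the nearest replicate 1 peak. The other named unshared peaks of replicate 2, on chromosome 23 at 16204419 and chromosome 15 at 7218013, lay 4855 and 73 bp from one.

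The second comparison asks whether sites found in both replicates were the stronger ones of each list. The lists were cut into 4 parts of equal size by −log10 q. In the best part of replicate 1, which holds the named sites on chromosomes 22, 11 and 17, 94 of 95 peaks (98.9%) were shared, and in the last part 67 of 95 (70.5%). For replicate 2 these shares were 192 of 274 (70.1%) and 16 of 274 (5.84%). Median −log10 q was 11.9 for shared and 7.41 for unshared peaks in replicate 1, a difference of 4.45 (permutation p = 0.00043, adjusted 0.00043). In replicate 2 these medians were 13.8 and 6.91, a difference of 6.84 (permutation p = 1e-05, the smallest possible, adjusted 2e-05). An alternative chosen after seeing the data kept only windows under 4 times the mean tag density. There the difference between shared and unshared peaks was 2.57 in replicate 1 (permutation p = 0.0232) and 6.44 in replicate 2 (permutation p = 1e-05). Fold enrichment did not separate them. Its medians were 6.459 for shared and 6.474 for unshared peaks in replicate 1 (permutation p = 0.988), and 6.374 and 6.327 in replicate 2 (permutation p = 0.721). Pileup did, with medians of 32 against 17 tags in replicate 1 and 36 against 15 in replicate 2 (permutation p = 1e-05 in each). All these tests treat neighbouring peaks as independent, so their p-values may be too small.

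The third comparison asks how the sites were spread over the chromosomes. Counted peak by peak, chromosomes 2, 4 and 8 held more peaks than their length gives in both lists. Once peaks within 100 kb were merged, only chromosome 4 passed the test, and in replicate 1 alone. Chromosome 4 had 32 peaks in replicate 1 and 87 in replicate 2, 1.83 and 1.73 times the number its length gives (exact binomial test, adjusted p = 0.0104 and 4e-05). For chromosome 2 the numbers were 29 and 78, 1.78 and 1.66 times (exact binomial test, adjusted p = 0.0184 and 0.000243), and for chromosome 8 they were 30 and 65, 1.89 and 1.42 times (exact binomial test, adjusted p = 0.0104 and 0.0424). Chromosome 7 was higher in replicate 1, at 36 peaks and 1.66 times, and did not pass the test in replicate 2, at 72 peaks and 1.15 times. Fewer peaks than length gives were found on chromosomes 6, 9 and 25 in replicate 1 and on chromosomes 1 and 14 in replicate 2.

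**Figure D1:**
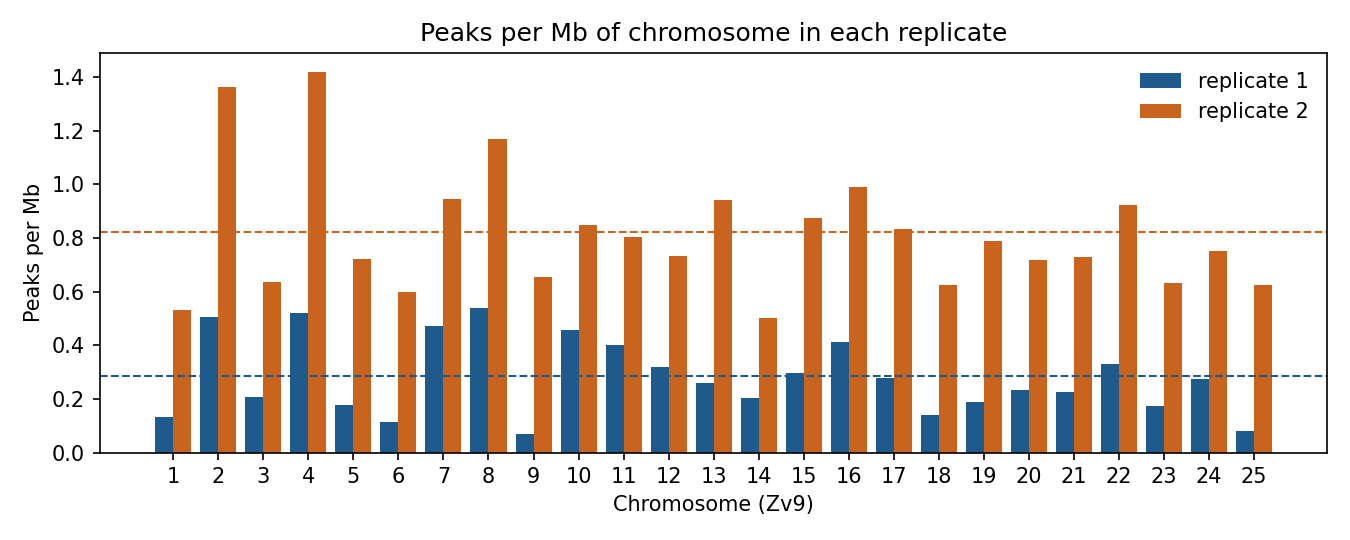
Peaks per Mb on each of the 25 Zv9 chromosomes (x axis) in replicate 1 and replicate 2 (y axis, bars), with chromosome length taken as the furthest peak end and dashed lines at each list's own mean of 0.285 and 0.823 peaks per Mb. Chromosomes 2, 4 and 8, which passed the test peak by peak in both lists, stand above the line in both, chromosome 4 at 0.522 and 1.42 peaks per Mb. Chromosomes 7, 10, 15, 16 and 22 also stand above both lines, without passing in both lists.

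Between the replicates, none of the 25 chromosomes differed in its share of the list after adjustment. Chromosome 9 alone had an unadjusted p under 0.05, with 4 of 380 peaks (1.05%) against 38 of 1096 (3.47%) (Fisher's exact test, p = 0.0119, adjusted 0.297). Fisher's test treats the lists as independent, although 330 of the 380 replicate 1 peaks met a replicate 2 peak. Sites in both lists draw the shares together, so the lack of a difference is weak evidence. The tests against length also count each peak separately, and many peaks are neighbours. When peaks within 100 kb were first merged, a choice made after seeing the data, chromosome 4 alone passed, in replicate 1 (21 regions, 2.17 times, exact binomial test, adjusted p = 0.0205), while in replicate 2 it had 47 regions, 1.49 times (adjusted p = 0.195). Merged in this way, chromosome 2 stood at 1.22 and 1.29 times and chromosome 8 at 1.03 and 0.877 times, below its length in replicate 2, and neither passed in either list.

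The fourth comparison asks whether sites lay in local clusters. The window with the most peaks was on chromosome 8 between 35907786 and 35950254, with 11 peaks in each replicate, of which all 11 in replicate 1 and 10 in replicate 2 were shared. On chromosome 10 between 16737251 and 16797501, replicate 1 had 8 peaks, all shared, and replicate 2 had 11, of which 7 were shared. A further cluster on chromosome 8, between 36401693 and 36441996, held 5 and 10 peaks, and one on chromosome 21 between 25219715 and 25255738 held 4 and 10. Chromosome 2 had 3 of the named windows, at 18573448 to 18595379 (4 and 9 peaks), 19008730 to 19028246 (6 and 8) and 14511664 to 14587077 (4 and 8). The remaining named windows were on chromosome 16 at 28154783 to 28179380 (3 and 9 peaks), chromosome 4 at 28002036 to 28016168 (2 and 9) and chromosome 10 at 12014543 to 12050451 (8 and 7). All the named windows were dense. The median tag density around their peaks ranged from 8.64 times the genome mean (chromosome 21, replicate 1) to 38.0 times (chromosome 4, replicate 2). No control sample was used and clustering was not tested apart in windows of low density. How far the clusters reflect accessibility rather than tag density is therefore not known.

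**Figure D2:**
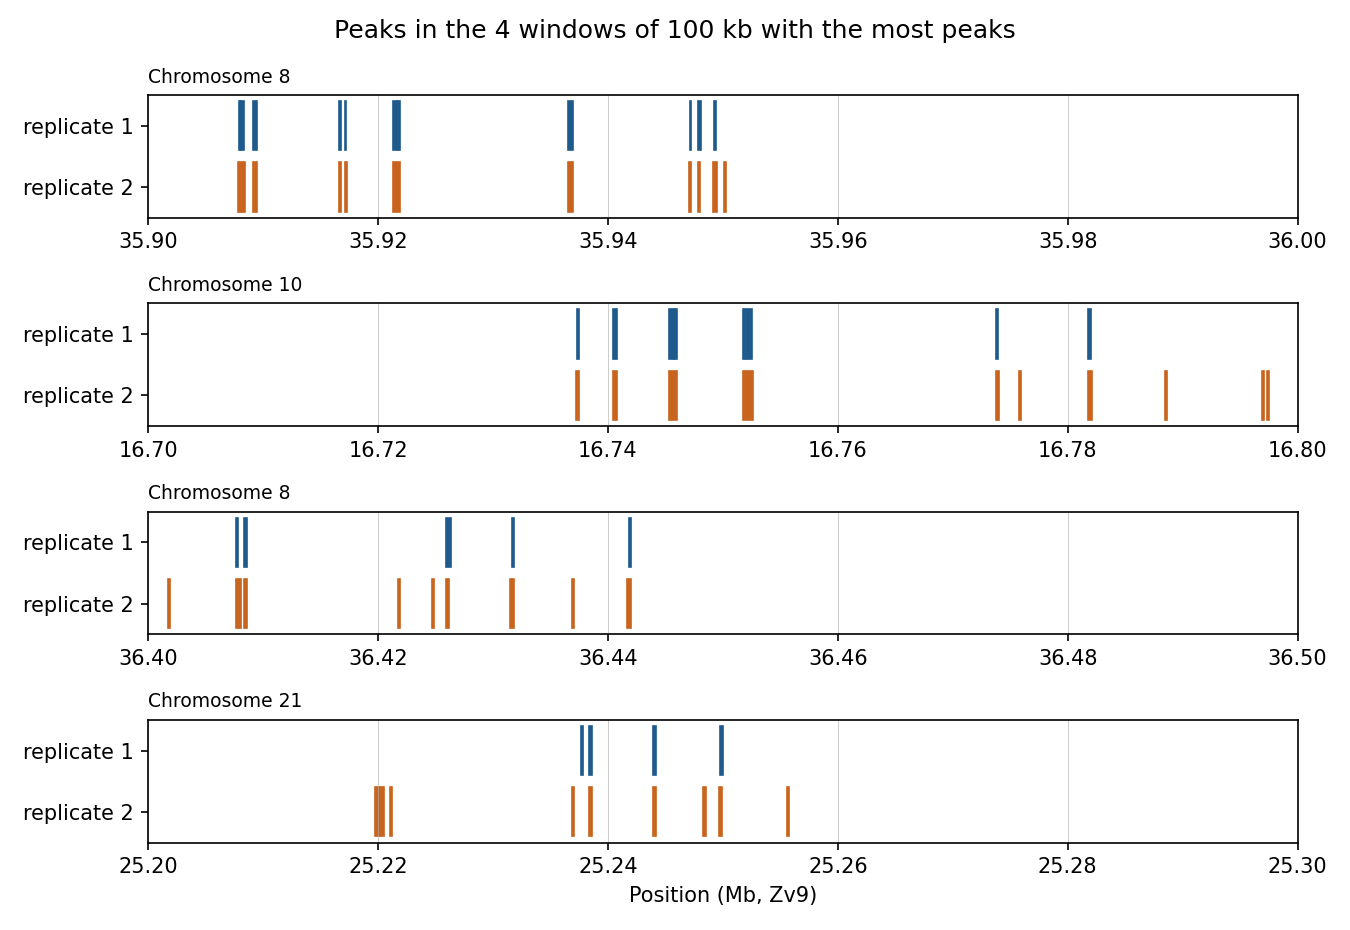
Positions of replicate 1 and replicate 2 peaks (bars, rows) along the 4 windows of 100 kb with the most peaks, on chromosomes 8, 10, 8 and 21 (x axis, Mb on Zv9). In the top window, on chromosome 8, both rows hold 11 peaks, some too close to be drawn apart, whereas on chromosome 21 replicate 2 has 10 peaks and replicate 1 has 4.

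In replicate 1, 210 of 380 peaks (55.3%, interval 50.2 to 60.2) had a neighbour within 10 kb, against a chance median of 2 and maximum of 16. In replicate 2 it was 444 of 1096 (40.5%, interval 37.6 to 43.4), against a median of 18 and maximum of 52 (permutation p = 0.0001 in each, the smallest possible). With peaks within 1 kb merged first, the share was 102 of 303 (33.7%) in replicate 1 and 186 of 920 (20.2%) in replicate 2, against chance maxima of 14 and 36. At least 5 peaks in 1 list were found in 28 windows, 10 of them in replicate 1, 25 in replicate 2 and 7 in both. Even so, most regions were single peaks once peaks within 100 kb were joined, 138 of 210 in replicate 1 and 512 of 684 in replicate 2. Merging peaks within 1 kb brought the named windows at chromosome 8, 35907786, chromosome 10, 12014543, and chromosome 2, 19008730, down to 6, 4 and 5 peaks (from 11, 8 and 8, in the list that had more, or in replicate 2 at equal numbers). After this merging, the window on chromosome 10 at 16737251 held the most peaks of the named windows, with 9.

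A last comparison, chosen after seeing the data, concerns the tag density in the 10 kb around shared sites, as a multiple of each sample's own mean. The regions with 3 or more shared peaks in dense windows (at least 4 times the mean in replicate 1) numbered 24, and they fell on both sides. On chromosome 8 at 35907851 to 35949396 the median density was 16.5 times the mean in replicate 1 and 22.3 in replicate 2, and the median ratio of replicate 2 to replicate 1 was 1.55 (range 1.35 to 1.58 over 9 peaks). Ratios were also high on chromosome 21 at 25238355 to 25249975 (1.52), chromosome 8 at 45715951 to 45748709 (1.51), chromosome 2 at 18988304 to 19028187 (1.46) and chromosome 4 at 27873404 to 28008374 (1.38, highest 1.81). They were below 1 on chromosome 11 at 15193960 to 15195481 (0.799), chromosome 23 at 7821553 to 7823024 (0.825), chromosome 16 at 16637382 to 16640335 (0.857) and chromosome 10 at 12014554 to 12050442 (0.879).

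**Figure D3:**
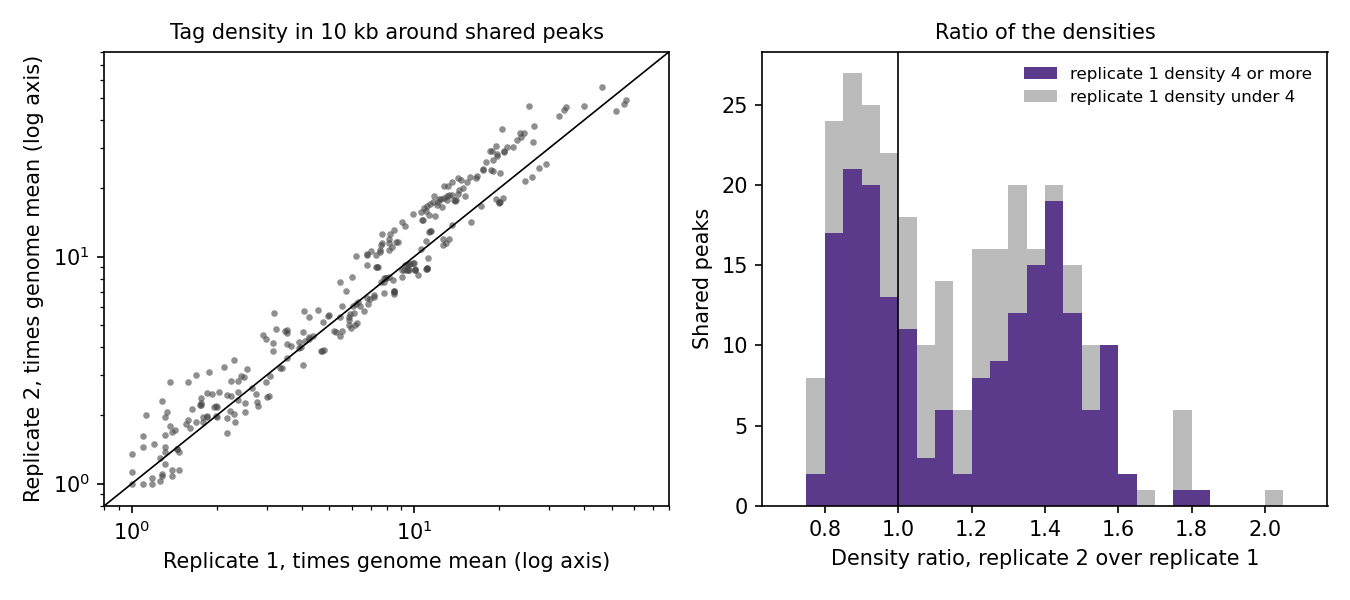
Left, tag density in 10 kb around each of the 288 shared peaks whose summits lay within 100 bp, in replicate 1 (x axis) and replicate 2 (y axis), as multiples of the sample's mean on log axes, with a line where both are equal. Right, the number of these peaks (y axis) by density ratio of replicate 2 to replicate 1 (x axis), dark where replicate 1 was at least 4 times its mean and grey where lower, with few dark ratios between 1.1 and 1.2 and most on either side.

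Of the 24 regions, 10 span less than 10 kb, among them those named on chromosomes 11, 23 and 16, so their windows hold largely the same tags and their ratios are nearly 1 measurement. In the other 14, every ratio was above 1.2 in 9 regions and below 1.1 in 4, and 1 had others. Over all 288 pairs the median ratio was 1.135 (quartiles 0.932 and 1.38). Among 115 dense windows that do not overlap, 57 had a ratio above 1.2 (median 1.41), 53 a ratio below 1.1 (median 0.929) and 5 lay between. Dense windows were chosen by replicate 1, the denominator of the ratio, so windows dense only in replicate 2 were left out. Near the limit this choice favours low ratios, and the split of 57 against 53 depends on it. For 39 of the 115 (33.9%, exact interval 25.3 to 43.3) the whole 95% interval of the ratio was above 1.2. The exact interval treats windows as independent, although windows of the same region had similar ratios, so it is too narrow. With 1 library per replicate, these ratios compare the libraries, and nothing measures how far other libraries of the same stage would differ.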

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

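The tag density around peaks was not among the planned comparisons, and the result given next was picked out from it after the values were seen. The start of chromosome 1 held far more tags than any other peak region. The peak at 79 to 1886 in replicate 1 had 7003 deduplicated tags in 10 kb, 187 times the genome mean, and the one at 65 to 1949 in replicate 2 had 8968, 220 times the mean. These peaks lie at the chromosome end, so part of the 10 kb window holds no sequence. Pileups there were 227 and 235 tags, while fold enrichment over the surrounding density was 2.19 and 1.78. Keeping at most 1 tag per position limits the pileup where tags are this dense. The fold enrichments are limited in the same way and may understate the peaks. The next densest peak regions had 2094 tags (chromosome 16 at 16637382 to 16637735, replicate 1) and 2274 tags (chromosome 4 at 61304172 to 61305214, replicate 2). No explanation was tested for the chromosome 1 region.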

How the results depend on the processing

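Sharing passed its test under every alternative run, from 63.4% of replicate 1 peaks with equally long lists to 92.6% with the top part of each list, and 74.2% at a reciprocal overlap of 50%. Chosen after seeing the data, placement within 5 kb gave at most 68 shared peaks by chance, and windows under 4 times the mean density 79.4% sharing. By fold enrichment, the difference between shared and unshared peaks was -0.014 in replicate 1, reversed in sign, and 0.0475 in replicate 2, neither past the threshold, and the cause was not tested. For chromosomes against length, both lists pooled gave 10 calls, single lists 5 to 7 (5 without replicate 1), and merging within 100 kb, added after seeing the data, 1. In the pooled lists a shared site is counted from each list, so they hold fewer distinct sites than peaks. Merging leaves fewer units to test, and the cause was not tested further. Clustering and the comparison of chromosomes between replicates kept their side of the threshold in every alternative run, but the clustered share was lower with neighbours within 1 kb (32.1% and 25.6%) and with peaks within 1 kb merged (33.7% and 20.2%). In windows under 4 times the mean density, the difference in −log10 q was 2.57 in replicate 1 and 6.44 in replicate 2. Of the 20 named shared peaks, 19 overlapped reciprocally by 50% (chromosome 24 at 11726472, 48.8%). Leaving out a replicate gives no value for sharing or rank. Tests at start sites, of gene lists and of base composition, and their alternatives, were not run. No paired analysis was possible because there is 1 group. How depth acts on weak against strong peaks was not tested, and the lowest pileups in the lists were 10 tags in replicate 1 and 7 in replicate 2.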

Other observations

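Except for the scaling of replicate 2 to the depth of replicate 1, all tests in this part were chosen after the result was seen, as were the limits of 4 times the mean, 1.2, 1.1, 100 bp and 200 kb. Tag density in the 10 kb around a peak includes the peak's own tags and cannot fall below the genome mean, and it was not compared with random windows. Median density around peaks was 6.77 times the genome mean in replicate 1 (quartiles 2.47 and 12.2) and 2.60 times in replicate 2 (quartiles 1.52 and 8.57). Over the better ranked part of each list, the top 50% by −log10 q, it was 7.41 and 4.65 times, so the gap between the lists depends in part on the weaker peaks of replicate 2. At least 4 times the mean was reached at 244 of 380 peaks (64.2%) and 421 of 1096 (38.4%). Shared peaks had a higher median density than unshared ones, 7.34 against 2.89 in replicate 1 (permutation p = 0.00154) and 7.70 against 2.01 in replicate 2 (permutation p = 1e-05). Both tests shuffle single peaks, although neighbours within 10 kb hold many of the same tags, so these p-values may be too small. The strong shared site on chromosome 2 at 57209228 to 57209415 had fold enrichments of 21.9 and 25.1 at low densities of 1.34 and 2.06 times the mean.

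Replicate 2 had 2.88 times as many peaks as replicate 1. A looser cut-off is not the whole cause, since 1067 of its 1096 peaks reached the lowest −log10 p of the replicate 1 list (7.94). Depth alone is not either, since 988 still did after pileup and density were scaled down to the depth of replicate 1. Peaks found only in replicate 2 were not placed at random, as 144 of 774 (18.6%) lay within 10 kb of a replicate 1 peak, against at most 12 by chance, but nothing was tested about the others. A difference in library quality, batch or exact stage may contribute, and with 1 library per replicate these cannot be told apart.

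The density ratio between the replicates differed by region, as on chromosome 8 near 35907851 (1.55) and chromosome 11 near 15193960 (0.799). Depth and counting error alone cannot give this, since chi-square over degrees of freedom was 7.63 for 206 windows that do not overlap. Extra copies of sequence equal in both samples predict a ratio of 1 if scaling by the genome mean holds in both, which was not checked. Under that scaling, the 33.9% of dense windows whose whole interval lay above 1.2 argue against equal copies as their sole cause. A property of regions wider than 10 kb is consistent with the intraclass correlation of the log2 ratio, 0.898 over 48 windows in 18 regions (permutation p = 0.0001, the smallest possible), and where the first window of a region was above 1.2, all 20 further windows were too. Equal extra copies were not decided for windows below 1.1 as a group. Under the same scaling, some of these windows had intervals wholly below 1, which goes against a ratio of 1 there. Others had intervals that included 1, and the windows of either kind were not counted. Where the first window of a region was below 1.1, 6 of 7 further windows stayed below. Chi-square over degrees of freedom for these 7 was 1.62 (p = 0.137), too few windows to decide. That test asked whether the further windows had the same ratio, not whether the ratio was 1. An earlier form of that test used windows already chosen by their ratio and was dropped as void, the lower limit was also moved once, to a rounder number, which left this test at the same value, and base composition, amplification, batch (the alignment names carry different day tags), copy number differing between embryo pools and a small difference in stage or accessibility were not tested.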
